A study of Mus musculus with 6 samples.

How the data were processed

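Gene expression was measured by poly-A RNA sequencing of mouse distal colon in 6 libraries, 3 labelled wild-type and 3 labelled Itgbl1 knockout. All animals drank water with DSS, the salt dextran sulfate sodium of 36 to 50 kDa, at 3% for 7 days, per the labels' protocols. Library inserts were selected at about 370 to 420 bp, and the labels give 1 date for all 6 libraries. Nothing in the labels says how the knockout allele was made, and whether each library came from a separate animal is given only as a replicate number, so p-values measure the spread between these samples.

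The deposited table holds whole-number counts per gene, 1 column per library, which the authors made from reads trimmed of adaptors, poly-N reads and low-quality reads, per the labels' protocols. HISAT2 2.0.5, StringTie 1.3.3b, featureCounts 1.5.0-p3 and DESeq2 are named in the submitters' processing notes with no roles, together with the builds GRCm38 and mm10. The annotation release, the strand setting and the treatment of reads that map to several genes are not given in the sources used here, so reads of overlapping or near-identical genes could be assigned to either. The deposited table lists 54532 genes with their coordinates, of which 54495 identifiers were found in GENCODE M21 for GRCm38, and 53585 of those (98.3%) had the same start and end. Of the 686 symbols in the gene lists, all were found, 2 of them under an older name through a RefSeq table for GRCm38.p6.

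Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 16861 genes. Libraries were scaled by TMM, and the groups were compared with the robust quasi-likelihood F test, without covariates. P-values were adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. CPM values are counts scaled to a common total by the TMM-scaled library sizes. Log2 CPM uses a prior count of 2. Gene lists were tested with camera from limma 3.58.1, two-sided, with a preset inter-gene correlation of 0.01 and adjustment over the 38 lists that had at least 5 tested members, the sex markers excepted. Single values per library were compared by a two-sided exact permutation test, whose smallest p for 3 libraries against 3 is 0.1.

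The groups, tests, gene lists and most alternatives were fixed before the data were examined. The rule for named genes took Itgbl1, then up to 10 higher and 10 lower genes past the threshold with at least a 2-fold change, a mean of at least 1 CPM, no overlap of the groups, a protein-coding biotype and a symbol that is neither predicted nor an immune receptor segment. Where fewer passed, the genes with the smallest p filled the list up to 5 per direction, with the words that they did not pass. From each list up to 4 members with the smallest p could be named: 4 were taken from the lists on epithelium and cytokines and 3 from each other list past its test. Genes outside this rule are said to be chosen after their values were seen.

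The quasi-likelihood test and camera were checked on simulated counts drawn from the means and library sizes of these libraries, with 200 genes changed in the knockout against wild-type comparison. At the gene-wise spread of these libraries, over 16514 genes, the quasi-likelihood test recovered 0 of 66 genes changed 2-fold, 8 of 66 changed 4-fold and 34 of 64 changed 8-fold, with 2 false calls. At a dispersion of 0.05, over 16673 genes, it recovered 36 of 67, 65 of 67 and 64 of 64, with 5 false calls. A simulated list of 25 genes lowered 2-fold gave a camera p of 2.8e-13, and an unchanged list of 24 genes gave 0.695, both over 16515 genes. Simulated genes were drawn independently, so this does not check camera on lists whose genes move together. Estimated correlations in the real data were 0.549 for junctions, 0.769 for colonocytes and 0.817 for goblet cells.

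Alternatives covered RLE and upper-quartile scaling, no filter, a filter of at least 10 reads in every library, each library left out in turn, and a replicate block. Other tests were DESeq2 1.42.0 with its own filter, limma-voom with and without quality weights, and glmTreat against a 1.5-fold change. Protein-coding genes alone, and all genes without immune receptor and mitochondrial genes, were also tested. Camera was repeated with an estimated correlation and on ranks. Fry tested whether the genes of a list move on balance one way, without comparing them with other genes. Leaving out KO 3 and WT 2 together, the other quasi-likelihood fit of edgeR and the fit without the robust option were added after the data were seen. Within each group, counts of all library pairs differed by far more than sampling noise, with a chi-square per degree of freedom of 50.7 to 253 over genes with at least 20 reads in the pair, so no library was counted as a copy of another.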

Results

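RNA sequencing of distal colon compared 3 libraries labelled wild-type (WT 1 to WT 3) with 3 labelled Itgbl1 knockout (KO 1 to KO 3) after 7 days of DSS, a polymer that injures the colonic epithelium and causes colitis. The series title names protection of the epithelium as its subject, so the comparison asks how transcripts of epithelium and inflammation differ between the labels. Gene counts totalled 18321389, 16800399 and 17270693 in WT 1, WT 2 and WT 3. They totalled 16844543, 17465473 and 13326970 in KO 1, KO 2 and KO 3.

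Itgbl1, which encodes a secreted protein resembling integrin beta subunits, showed no detectable loss in the libraries labelled knockout. The gene (ENSMUSG00000032925, chromosome 14, 123659971 to 123975618, GRCm38) had 19, 6 and 5 reads in WT 1 to WT 3 and 12, 4 and 10 reads in KO 1 to KO 3. Means were 0.601 ± 0.459 CPM (SD, n = 3) under the wild-type label and 0.533 ± 0.279 CPM (SD, n = 3) under the knockout label. The ratio was 0.878 with a 95% interval of 0.25 to 3.08 (edgeR quasi-likelihood, adjusted p = 0.9). A ratio below 0.25 was outside the interval, and losses that leave a ratio above 0.25 were not detectable at this depth. A count over the whole gene does not show which exons were read, and the deleted part is not described in the labels. The count therefore does not bear out the knockout label, and every direction given here is between libraries labelled knockout and libraries labelled wild-type.

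**Figure D1:**
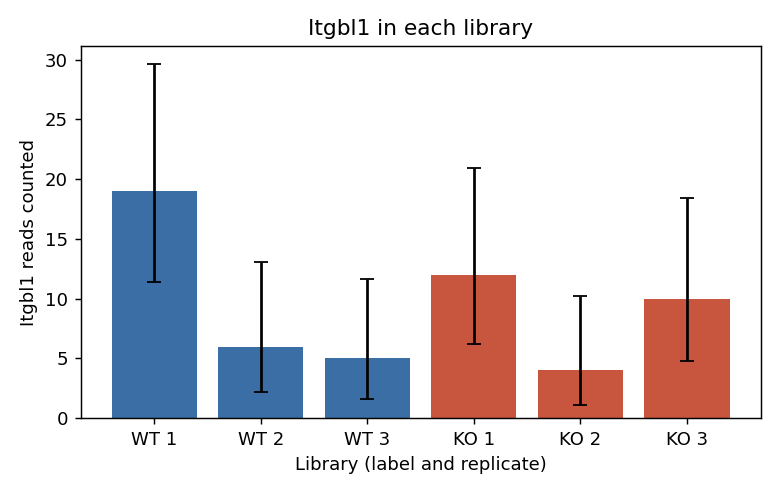
Reads counted for Itgbl1 (vertical axis) in each library (horizontal axis), with blue bars for the wild-type label, red bars for the knockout label and error bars for exact Poisson 95% intervals, which cover counting error only. The bars of 12, 4 and 10 reads under the knockout label lie within the range of the 19, 6 and 5 reads under the wild-type label or, for the lowest, just below it.

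Epithelial transcripts differed widely between the libraries labelled knockout. Relative to the wild-type mean, the median absorptive colonocyte gene stood at -3.68 in KO 1, -1.09 in KO 2 and -7.56 in KO 3 on the log2 scale. WT 1 to WT 3 stood at 0.03, 0.0021 and -0.027. These are medians of deviations from the wild-type mean, so opposite moves of single genes can cancel in them. Across 16861 tested genes the first principal component held 65.7% of the variance, with WT 1 to WT 3 at -58.0, -109.7 and -76.9 and KO 1 to KO 3 at 70.5, 2.47 and 171.6. The exact permutation p of that component was 0.1, the smallest that 3 against 3 allows. Pearson correlations of log2 CPM across genes, which are not independent replicates, were 0.93 to 0.97 between wild-type libraries, 0.82 to 0.90 between libraries labelled knockout and 0.67 to 0.94 between labels.

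Mitochondrially encoded genes took 12.8% of the counts in KO 3 and 3.53 to 4.88% in the other 5 libraries, and the 10 most abundant genes took 15.4% in KO 3. Immunoglobulin genes took 4.03% of the counts in KO 1 and 0.388 to 0.94% in the other libraries. By exact permutation test the groups gave p = 0.2 for the mitochondrial share, 0.1 for the 10 most abundant genes, 0.9 for immunoglobulin genes, 0.5 for total counts and 0.7 for the number of genes detected. After adjustment over 6 such measures, the smallest value was 0.3.

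No single gene passed the adjusted threshold in the comparison of the labels, and Gk and Esm1 were the lower and the higher protein-coding gene with the smallest p. Gk, which encodes glycerol kinase, was at 130.9 ± 13.5 CPM (SD, n = 3) under the wild-type label and 20.8 ± 4.11 CPM (SD, n = 3) under the knockout label. Esm1, which encodes the endothelial proteoglycan endocan, was at 1.54 ± 0.473 and 22.6 ± 9.96 CPM (SD, n = 3 each). With edgeR's quasi-likelihood test 0 of 16861 genes had an adjusted p under 0.05, the smallest being 0.094, and 4059 had an unadjusted p under 0.05, of which 1992 were higher and 2067 lower under the knockout label. That balance moved to 2673 higher and 1691 lower with upper-quartile scaling and to 1701 higher and 2399 lower with limma-voom. DESeq2 called 2029 genes (779 higher, 1250 lower), limma-voom 0, and limma-voom with quality weights 1395 (376 higher, 1019 lower). Without KO 2 the quasi-likelihood test called 1813 genes (460 higher, 1353 lower), without KO 3 it called 0, and with no filter on low counts it called 192. In 5451 genes (32.3%) the libraries of the labels did not overlap, against 10% by chance.

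The 5 lower protein-coding genes with the smallest p did not pass, each with an adjusted p of 0.094 by edgeR. Their log2 ratios were -2.65 ± 0.26 (SE) for Gk (ENSMUSG00000025059, chromosome X, 85701937 to 85776819) and -3.48 ± 0.36 for the glutamate transporter gene Slc1a1 (ENSMUSG00000024935, chromosome 19, 28835049 to 28913960). Lrrc19 (ENSMUSG00000049799, chromosome 4, 94636653 to 94650144) was at -4.89 ± 0.53. Mtm1, a phosphoinositide phosphatase gene (ENSMUSG00000031337, chromosome X, 71210767 to 71315691), was at -2.19 ± 0.25, and Trpm6, a magnesium channel gene (ENSMUSG00000024727, chromosome 19, 18749983 to 18892510), at -4.12 ± 0.50. The 5 higher protein-coding genes with the smallest p did not pass either, at the same adjusted p. Esm1 (ENSMUSG00000042379, chromosome 13, 113209659 to 113218098) had a log2 ratio of 3.87 ± 0.49, and the agouti signalling gene a (ENSMUSG00000027596, chromosome 2, 154791402 to 155051012) had 3.81 ± 0.48. Acat3 (ENSMUSG00000062480, chromosome 17, 12923813 to 12940600) had 3.02 ± 0.44, the protease inhibitor gene Serpine2 (ENSMUSG00000026249, chromosome 1, 79794197 to 79861180) 3.10 ± 0.48, and the platelet chemokine gene Pf4 (ENSMUSG00000029373, chromosome 5, 90772435 to 90773383) 2.64 ± 0.42.

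**Figure D2:**
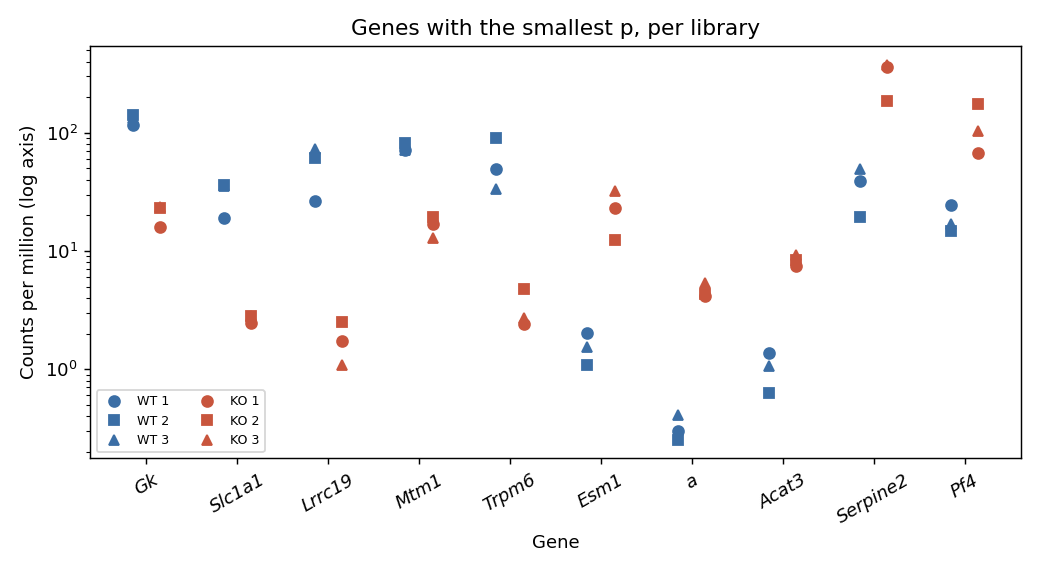
CPM on a log axis (vertical) for the 5 lower and 5 higher protein-coding genes with the smallest p (horizontal), with 1 point per library, blue for the wild-type label and red for the knockout label. The labels do not overlap in any of these genes, which were selected for that, and none passed the adjusted threshold, the adjusted p being 0.094 for each.

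Lists of epithelial genes were lower as sets in the libraries labelled knockout. Of 27 junction genes, 26 had a negative log2 ratio, with a median of -2.16 (camera adjusted p = 1.23e-10). All 27 absorptive colonocyte genes were negative with a median of -2.49 (2.18e-10), and all 15 goblet cell and mucus genes with a median of -2.05 (9.06e-06). With an estimated correlation none of these calls held, at p = 0.116 for junctions, 0.171 for colonocytes and 0.22 for goblet cells. Without KO 2 the medians were -3.36, -4.64 and -5.29 in the same order. No member passed over all genes, while 6 junction genes, 2 colonocyte genes and 2 goblet cell genes passed, all lower, when adjusted over the list alone.

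Among junction genes the claudin gene Cldn8 was at 108.6, 101.7 and 143.1 CPM in WT 1 to WT 3 and at 4.79, 8.35 and 1.01 CPM in KO 1 to KO 3, a log2 ratio of -4.63. Ctnnd1, which encodes p120 catenin, had a log2 ratio of -1.36, Cldn12 one of -1.66 and the polarity gene Patj one of -2.30, and all 4 fell when adjusted over the list alone. Car2, a carbonic anhydrase gene, and Slc26a3, the chloride and bicarbonate exchanger of surface colonocytes, fell when adjusted over the list alone, with log2 ratios of -4.70 and -4.77. Both varied under the wild-type label. In WT 1 to WT 3 Car2 was at 279.1, 1537 and 398.8 CPM and Slc26a3 at 560.8, 1200 and 387.1 CPM. Slc37a2 at -4.13 and the guanylin family gene Guca2b at -3.37 did not pass. In the goblet cell list the transcription factor genes Creb3l1 and Klf4 fell when adjusted over the list alone, with log2 ratios of -2.41 and -2.44. The mucin gene Muc13 at -2.94 and the disulfide isomerase gene Agr2 at -3.29 did not pass. The median goblet cell gene was at -4.25 in KO 1, -0.53 in KO 2 and -8.47 in KO 3 relative to the wild-type mean. Of the 15 goblet cell genes, 7 were lower in all 3 libraries labelled knockout than in every wild-type library. The others overlapped, among them Muc2 at 2197 CPM in KO 2 against 2704, 2152 and 2311 CPM in WT 1 to WT 3. KO 3 was also the library with 12.8% mitochondrial counts.

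The inflammatory cytokine list was higher as a set, with 12 of 18 members positive and a median of 1.56 (camera adjusted p = 0.028, and p = 0.401 with an estimated correlation). Its member with the smallest p went the other way: Il18, a cytokine made by epithelium, fell by 4.05 on the log2 scale and was the 1 member past the test adjusted over the list alone. Tnfsf11 at 2.89, Osm at 2.90 and Il6 at 4.94 did not pass. Il6 was at 508.3 CPM in KO 3, 42.7 in KO 1 and 23.1 in KO 2 against 11.9, 0.127 and 6.61 in WT 1 to WT 3. Relative to the wild-type mean, the median member was at 1.48, -1.59 and 0.023 in WT 1 to WT 3. In KO 1 to KO 3 it was at 1.68, 1.87 and 2.38, so WT 1 lay close to KO 1. The median log2 ratio was 3.09 without WT 1, 0.88 without WT 2 and 0.82 without KO 3. The call ended without WT 2 (adjusted p = 0.148), without KO 2 (0.085), without KO 3 (0.0769), with upper-quartile scaling (0.0724) and with the strict filter (0.692). Over its alternatives the adjusted p reached 0.726.

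**Figure D3:**
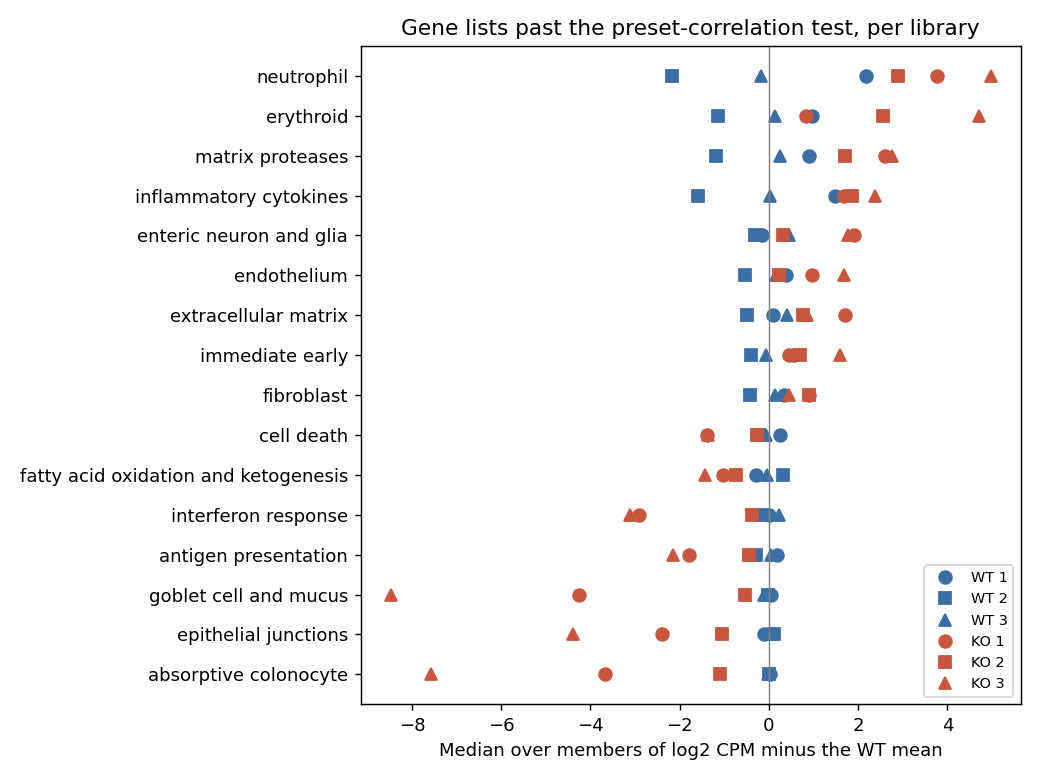
Median over list members of log2 CPM minus the wild-type mean (horizontal axis) for the 16 gene lists past the preset-correlation test (vertical axis), with 1 point per library, blue for the wild-type label and red for the knockout label. KO 3 and KO 1 lie farther from 0 than KO 2 in the goblet cell list, at -8.47 and -4.25 against -0.53.

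Neutrophil, matrix and vessel genes were higher as sets in the libraries labelled knockout. The neutrophil list had 14 of 16 members positive and a median of 3.55 (camera adjusted p = 1.39e-06, and p = 0.16 with an estimated correlation), and 7 members passed when adjusted over the list alone. Of these, the collagenase and gelatinase genes Mmp8 and Mmp9 rose by 4.28 and 3.94 on the log2 scale, and the granule gene Ngp rose by 7.45. Ngp was at 73.6, 6.52 and 444.8 CPM in KO 1 to KO 3 and at 2.62, 0 and 0.354 CPM in WT 1 to WT 3. The 2 negative members, named after their values were seen, were the marker Ly6g at -1.55 and Ltf at -0.38. Ly6g was at 1704, 471.8 and 897.7 CPM in WT 1 to WT 3. In KO 1 to KO 3 it was at 206.6, 832.3 and 10.7 CPM. Neutrophil transcripts also varied within the wild-type label, with the median member at 2.17 in WT 1, -2.18 in WT 2 and -0.18 in WT 3 relative to the wild-type mean. All 13 matrix protease genes were positive with a median of 2.13 (6.2e-07, and p = 0.0692 with an estimated correlation). In that list 9 passed when adjusted over the list alone, among them Adamts5 at 2.24, Mmp10 at 3.31 and Mmp13 at 2.97. Extracellular matrix genes were positive in 23 of 25 with a median of 1.11 (9.82e-07, and p = 0.151 with an estimated correlation), and 8 passed when adjusted over the list alone. These included the cross-linking enzyme gene Lox at 3.46, Lum at 1.15 and Dcn at 2.50.

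Enteric neuron and glia genes were positive in 17 of 18, with a median of 1.47 (camera adjusted p = 1.37e-05, and p = 0.18 with an estimated correlation), and 12 rose and 1 fell when adjusted over the list alone. The median member was at 1.91, 0.31 and 1.78 in KO 1 to KO 3 and at 0.45 in WT 3, so the labels overlapped. The glial gene Gfap rose by 2.98 and the neuronal gene Uchl1 by 1.41, while Erbb3, a receptor gene also used by epithelium, fell by 2.18. All 20 endothelial genes were positive with a median of 1.21 (3.15e-05, and p = 0.24 with an estimated correlation), yet 0 passed when adjusted over the list alone, against 9 at an unadjusted p under 0.05 by edgeR. Relative to the wild-type mean, the median endothelial gene was at 0.97, 0.22 and 1.69 in KO 1 to KO 3 and at 0.39 in WT 1, so KO 2 lay below WT 1. The call ended with KO 3 and WT 2 both left out, an alternative chosen after seeing the data (median 0.43, adjusted p = 0.0521, and 0.622 with an estimated correlation over all libraries). Examples were Prox1 at 1.25, Erg at 1.51 and Emcn at 2.46. All 6 erythroid genes were positive with a median of 3.28 (0.00229, and p = 0.222 with an estimated correlation), and 5 passed when adjusted over the list alone. These included Hba-a1 at 3.46, Hbb-bs at 3.62 and Alas2 at 2.89. The median erythroid gene was at 0.84, 2.56 and 4.72 in KO 1 to KO 3 and at 0.97 in WT 1, so KO 1 lay below WT 1. Fibroblast genes had a median of 0.80 (0.0113, and p = 0.193 with an estimated correlation) with 0 past the test adjusted over the list alone and 7 at an unadjusted p under 0.05 by edgeR. Pi16 was at 1.36, Grem1 at 2.11 and C3 at 2.07. Immediate early genes, which react to tissue handling, had a median of 1.00 (0.016, and p = 0.368 with an estimated correlation). Adjusted over the list alone 0 of 14 passed, and 4 had an unadjusted p under 0.05 by edgeR. Among all genes tested, 4059 of 16861 had an unadjusted p under 0.05, so 4 of 14 is near that share. Dusp1 was at 2.08, Nr4a1 at 1.60 and Ier3 at 2.85. The fibroblast call ended without KO 1 (median 0.50, adjusted p = 0.0924) and the immediate early call without KO 3 (median 0.48, adjusted p = 0.0833). Without KO 3 the medians were 0.64 for endothelium and 1.70 for erythroid genes, and both lists still passed. The median immediate early gene was at 0.45 in KO 1 and 0.56 in WT 1.

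Interferon, antigen presentation and lipid oxidation genes were lower as sets. Relative to the wild-type mean, the median interferon response gene was at -2.92, -0.37 and -3.12 in KO 1 to KO 3, and the median antigen presentation gene at -1.79, -0.46 and -2.15. KO 2 thus lay nearest to the wild-type libraries, as it did in the junction, colonocyte and goblet cell lists, with junction medians of -2.40, -1.06 and -4.40. All 24 interferon response genes were negative with a median of -1.38 (camera adjusted p = 3.6e-07, and p = 0.215 with an estimated correlation), and 3 fell when adjusted over the list alone. These were Cmpk2 at -2.48, Rsad2 at -1.84 and Stat2, which went from 159.4 to 64.8 CPM. All 15 antigen presentation genes were negative with a median of -1.39 (4e-05, and p = 0.229 with an estimated correlation). Adjusted over the list alone 0 passed, and 7 had an unadjusted p under 0.05 by edgeR, against 4059 of all 16861 genes tested. H2-DMa was at -1.48, H2-DMb1 at -2.06 and Nlrc5 at -0.97. Of 16 fatty acid oxidation and ketogenesis genes, 14 were negative with a median of -1.02 (0.000273, and p = 0.174 with an estimated correlation), and 10 fell and 1 rose when adjusted over the list alone. Among these were Ppargc1a at -3.27, Pparg at -1.85 and Cpt1a, the carnitine palmitoyltransferase gene, at -1.63. Cell death genes were negative in 17 of 22 with a median of -0.68 (0.0215, and p = 0.278 with an estimated correlation). The inflammasome genes Casp1 at -2.74 and Pycard at -2.14 fell when adjusted over the list alone, while Mlkl at -1.42 did not pass. The cell death call ended without WT 1 (median -0.44, adjusted p = 0.117) and without KO 1 (median -0.60, adjusted p = 0.156). Without KO 2 the medians were -1.34 for cell death and -3.24 for interferon response genes.

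The other 22 lists with a set test did not pass with the preset correlation. Median log2 ratios among process lists were 0.71 for TGF-beta signalling (camera adjusted p = 0.0901), -0.37 for stem and Wnt (0.0967), 0.29 for chemokines (0.24), and 0.82 for regenerative epithelium (0.376). They were 0.0055 for antimicrobial defence (0.69), -0.046 for the unfolded protein response (0.781), -0.093 for cell cycle (0.823), -0.33 for hypoxia and glycolysis (0.83) and 0.062 for integrins (0.964). Adjusted over the list alone, 3 TGF-beta genes and 3 integrin genes were higher and 3 of each were lower, while 1 stem and Wnt gene was higher and 5 were lower. By the same count 4 pancreatic acinar genes, 1 macrophage gene and 1 squamous gene were higher, 1 adipocyte gene and 1 mitochondrial gene were lower, and the other lists in this group had 0. Among cell type lists the medians were 5.74 for pancreatic acinar (0.0565), 0.64 for tuft cell (0.14), -0.91 for enteroendocrine (0.197), -0.78 for adipocyte (0.259), and -0.098 for T and NK cell (0.368). They were 0.68 for mesothelium (0.412), 0.80 for skeletal muscle (0.522), -0.30 for mast cell and eosinophil (0.6), 0.20 for B and plasma cell (0.69), -0.066 for smooth muscle (0.903) and -0.31 for macrophage and monocyte (0.944). Circadian clock genes had a median of -0.62 (0.102) and mitochondrially encoded genes one of 0.46 (0.69). The pancreatic acinar list passed without any 1 library except KO 2 (0.31), with adjusted p from 1.2e-11 without KO 3 (median 9.51) to 0.0351 without KO 1, and its median was at 3.21, 7.34 and 0.92 in KO 1 to KO 3. Without WT 1 the lists on chemokines (0.00821), stem and Wnt (0.00858) and the circadian clock (0.0222) passed, without WT 2 adipocyte (0.0168) and T and NK cell (0.0406), and without WT 3 TGF-beta signalling (0.0487). Without KO 1 chemokines passed (0.0294), without KO 2 enteroendocrine (0.0141), TGF-beta signalling (0.0261) and T and NK cell (0.0261), and without KO 3 mesothelium (0.0305) and smooth muscle (0.0407), the latter with its median turned to 0.34. For integrins, antimicrobial defence, smooth muscle and macrophage genes the set test pointed the opposite way from the median. Squamous epithelium had 4 tested genes and no set test, with a median of -0.52 and a mean of 0.049. Xist had 0 to 11 reads and Ddx3y 946 to 2463 reads in each of the 6 libraries, so the libraries did not differ in sex.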

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

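The alternative that left out both KO 3 and WT 2 was chosen after seeing the data. All 62 named genes other than Itgbl1 kept their direction under each alternative run on them. They were picked by smallest p from these same counts, so a kept direction says little about robustness. The lists on junctions, colonocytes and goblet cells kept direction and call. The exception was camera with an estimated correlation (p = 0.116, 0.171 and 0.22, medians -2.16, -2.49 and -2.05). Fry, which asks whether a list's genes move on balance one way and compares them with no other genes, gave an adjusted p of 0.2 for each. The number of genes called, 0 by edgeR with 4059 at an unadjusted p under 0.05, became 192 (29 higher, 163 lower) with no filter, 2029 (779 higher, 1250 lower) with DESeq2 and 1395 (376 higher, 1019 lower) with limma-voom and quality weights. It ranged from 0 to 1813 without 1 library each (0 to 460 higher, 0 to 1353 lower), the 1813 being without KO 2. It was 0 with RLE, upper-quartile, strict filter, glmTreat, limma-voom, protein-coding genes alone, immune receptor and mitochondrial genes left out, both other edgeR fits, and KO 3 and WT 2 both left out. The cause was not tested. Replicate numbers do not pair the libraries: same-numbered deviations correlated at -0.20, 0.087 and -0.075, and WT 3 correlated best with KO 1 at 0.34. The replicate block called 3 genes, all 3 lower (Tnni1, Hao2 and Dio1, named after their values were seen). The number of lists past camera was 16, became 0 with an estimated correlation, and was 15 to 19 in its other settings. By fry, which answers a different question, 0 lists passed, against 6 at an unadjusted p under 0.05.

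Upper-quartile scaling moved the median of all genes by 0.145 on the log2 scale. With it, cell cycle (0.050), the unfolded protein response (0.099), T and NK cell (0.036) and smooth muscle (0.067) turned positive. Antimicrobial defence turned negative with RLE (-0.015), no filter (-0.016), the strict filter (-0.47), the replicate block (-0.94) and with KO 3 and WT 2 both left out (-0.077). Integrins turned negative with the block (-0.023), mast cell and eosinophil positive with no filter (0.26) and with KO 3 and WT 2 left out (0.48), and smooth muscle positive there too (0.36). The cytokine list, at 1.56, lost its call with an estimated correlation (1.56), upper-quartile scaling (1.70), the strict filter (1.11), and KO 3 and WT 2 both left out (0.40), and it ranged from 0.82 to 3.09 without 1 library each. Itgbl1 turned to 0.33 with quality weights and ranged from -0.57 to 0.60 without 1 library each; with the strict filter it had no value. Genes near Itgbl1 had an odds ratio of 1.05 within 10 Mb and 0.83 within 20 Mb.

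Lists that did not pass gained a call in some settings (adjusted p given). These were pancreatic acinar with no filter (0.00028), the replicate block (0.00319), on ranks (0.0475), KO 3 and WT 2 both left out (8.17e-12), and without WT 1 (0.00666), WT 2 (0.00178), WT 3 (0.00317), KO 1 (0.0351) or KO 3 (1.2e-11). Chemokines passed without WT 1 (0.00821) or KO 1 (0.0294), and stem and Wnt without WT 1 (0.00858) and with the strict filter (0.0269). TGF-beta signalling passed without WT 3 (0.0487) or KO 2 (0.0261) and with the block (0.0479), T and NK cell without WT 2 (0.0406) or KO 2 (0.0261), and enteroendocrine without KO 2 (0.0141). Circadian clock passed without WT 1 (0.0222) and with no filter (0.0185). Adipocyte passed without WT 2 (0.0168) and with KO 3 and WT 2 both left out (0.0234), where mesothelium (0.00571) and smooth muscle (0.0304) also passed, and mesothelium (0.0305) and smooth muscle (0.0407, median 0.34) passed without KO 3. With KO 3 and WT 2 both left out, the endothelium (0.0521) and immediate early (0.186) lists lost their calls.

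Without 1 library each, medians of lists that did not pass also changed sign: the unfolded protein response (-0.28 to 0.050), hypoxia and glycolysis (-0.62 to 0.046), macrophage and monocyte (-0.89 to 0.058), T and NK cell (-0.65 to 0.12), mast cell and eosinophil (-0.60 to 0.47), tuft cell (-0.021 to 1.01), chemokines (-0.048 to 0.76), antimicrobial defence (-1.32 to 0.33), integrins (-0.32 to 0.19), B and plasma cell (-0.31 to 0.61), smooth muscle (-0.67 to 0.34), cell cycle (-0.39 to 0.17) and mitochondrially encoded genes (-0.0016 to 0.88). Itgbl1 had 4 to 19 reads per library, which limits how small a change in it could be detected.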

Other observations

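Transcripts typical of pancreas and liver varied between libraries, and their source was not settled. The genes given here were chosen after their values were seen. Pnlip, the pancreatic lipase gene, was at 223.7 CPM in KO 2, 16.6 in KO 1 and 0.699 in KO 3, and at 0 to 0.119 CPM under the wild-type label. Ctrb1, a chymotrypsinogen gene, was at 390.2, 22.4 and 1.01 CPM in the same libraries. A separate observation was Gm42031, a long noncoding RNA gene on chromosome 8 (85125872 to 85132289). It was at 33.2, 37.8 and 105.5 CPM in KO 1 to KO 3 and at 0.178, 0.0633 and 0 CPM in WT 1 to WT 3 (edgeR adjusted p = 0.094).

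In the tests that follow, those on KO 3 alone, on other cell types and on the knockout label for Alb were chosen after the values were seen. The 10 splits of 6 libraries into 3 and 3 are too few for a share under 0.05. The real split gave 4059 genes at an unadjusted p under 0.05 and the highest other split 895, so 1 of 10 reached the real count. The real split gave 16 lists past camera's preset correlation and the highest other split 21, so 7 of 10 reached it, and the number of lists past that test does not set the labels apart from other groupings.

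Epithelial lists were lower under the knockout label. A difference set by KO 3 alone is argued against, since KO 1 and KO 2 also lay below every wild-type library in the junction, colonocyte and goblet cell medians. Colonocyte medians were -3.68 in KO 1 and -1.09 in KO 2, and goblet cell medians -4.25 and -0.53. Without KO 3 the median over 69 members was -1.80 with a standard error of 0.15, against -2.33 with it. That standard error is over genes, which move together, and not over libraries. A lower share of epithelium raising all other cell types alike is argued against for these lists. In 20 of 36 pairs of cell type lists, medians lay apart by over 1 log2 unit and over 2 combined standard errors. The widest pair was neutrophil and macrophage at 3.86 with a combined standard error of 0.82, while the remaining pairs did not separate by that bound. Those standard errors are over genes, which move together within a list, and leave out the spread between libraries. The median neutrophil gene alone ran from -2.18 in WT 2 to 2.17 in WT 1. It was still higher in every library labelled knockout, at 3.77, 2.88 and 4.97 in KO 1 to KO 3. The median macrophage gene was at -0.30, 0.55 and -1.23 in KO 1 to KO 3. In WT 1 to WT 3 it was at 0.55, -0.56 and -0.016, so the labels overlapped. A lower share of epithelium together with other changes in cell types was not tested. Tissue from another segment of the colon stays open. Posterior minus anterior Hox genes differed by -1.65 with a standard error of 0.52 and no overlap of the labels. That met the criterion set beforehand. The values were 0.51, 1.36 and -0.37 in KO 1 to KO 3. They were 1.97, 2.42 and 2.06 in WT 1 to WT 3. Posterior genes were lower and anterior genes higher in every library labelled knockout than in every wild-type library. Mean log2 CPM of anterior genes was 3.15, 2.44 and 3.22 in KO 1 to KO 3. In WT 1 to WT 3 it was 1.94, 2.11 and 2.32. A loss of epithelium could lower posterior Hox genes too, which was not tested. That caveat does not cover the higher anterior genes, whose cause was not tested. An effect of the knockout also stays open and untested, because Itgbl1 reads do not bear out the label.

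Alb, the albumin gene, was at 522.3 CPM in KO 2, 483.5 in KO 3 and 43.1 in KO 1, and at 50.8, 1.01 and 2.89 in WT 1 to WT 3, with the lipoprotein gene Apoa1 at 55.0 and 59.0 CPM in KO 2 and KO 3. Liver RNA carried into some libraries is a candidate source, but the test on 24 hepatocyte genes does not decide it. Their ratio to Alb differed 94.4-fold over 5 libraries, beyond the bound set beforehand. That bound was judged wrong after the result was seen, because colon gives part of these counts. WT 2, with 16 Alb reads, had 1386 reads of them, 1026 from Tat and 218 from C4bp. Apart from Tat, C4bp and Apoc4, each gene had more reads in KO 2 and in KO 3 than in any wild-type library, as Alb did. That pattern was read after the values were seen, and a ratio without Tat, C4bp and Apoc4 was not tested. An effect of the knockout label is also undecided, since the lowest library labelled knockout was at 0.848 times the highest wild-type library and the other two were higher; a rule that 1 overlapping library excludes it was dropped after that value was seen.

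Flanking DNA of another strain around Itgbl1 could give differences near the gene. Because no gene passed the adjusted threshold, the test used genes at an unadjusted p under 0.05: 8 of 32 within 10 Mb (25%) against 24.1% of other genes, an odds ratio of 1.05 with a 95% interval of 0.408 to 2.42 (Fisher's exact test, two-sided, p = 0.839). The 2 groups of genes cannot be told apart with 32 genes in the window, which keeps this explanation open.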
